A study of Homo sapiens with 6 samples.

How the data were processed

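Poly(A) RNA of SKOV3 cells, an established human ovarian cancer line, was sequenced after 48 h with fenbendazole at 1 µM or with the solvent DMSO, in 3 libraries per group. The direction of every change rests on the submitters' labels. Libraries are named by group and by the number in their titles, DMSO 10, 11 and 12 and fenbendazole 7, 8 and 9. Total RNA was extracted with TRIzol and libraries were made with an NEB Ultra RNA kit, per the labels' protocols, which do not say whether strand was kept. Genes that overlap on opposite strands therefore cannot be separated with certainty.

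The deposited table holds whole-number read counts per gene that the authors did not normalise, and, per the file headers, FPKM values for the same 6 libraries. It lists 61552 genes by Ensembl identifier with GRCh38 coordinates, and 61399 identifiers matched the name table used here. Per the submitters' processing notes, CASAVA 1.8, HISAT2 2.1.0, StringTie 1.3.4b and edgeR were used with GRCh38. The counting program, its strand and multi-mapping settings and the annotation release are not given in the sources used here. Total counts ran from 13170775 (DMSO 12) to 22128930 (DMSO 11), so 3 counts in a library correspond to 0.136 to 0.228 CPM (counts scaled to a common library size). Every pair of replicates differed by more than sampling noise, with a chi-square per degree of freedom of at least 5.34, and none was treated as a repeat of another library.

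Counts were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test with robust dispersions, TMM scaling and edgeR's own filter on low counts, which left 17363 genes. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic. Levels are CPM on the TMM scale, as mean ± SD over 3 libraries. Gene lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over 33 lists with at least 3 tested members. One further list, the metallothionein genes, had 2 tested members and was not tested. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

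The gene lists, the tests, the first set of other settings and the rule for named genes were fixed before the data were examined. The rule took the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 5 CPM, groups that did not overlap and a gene symbol, then in each list up to 3 tested members with the smallest p. It added TUBB, TUBA1B, CYP1A1, CDKN1A, CCNB1, GAPDH, ACTB, HK2, SLC2A1 and MKI67 whatever their values, and the 5 genes with the highest level. It named 128 tested genes, of which those that carry the description are given. CYP1A1 did not pass the filter on low counts.

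Other settings fixed at that time were median-of-ratios and upper-quartile scaling, no filter, a filter of 1 CPM in all libraries of a group, the removal of mitochondrial and the 20 most abundant genes, leaving out each library, DESeq2 1.42.0, limma-voom, an adjusted p of 0.01, a test against a 1.5-fold change, a fold of at least 2, camera with an estimated correlation, and fry. Settings chosen after seeing the data were offsets for GC content and transcript length, limma-voom with library quality weights, limma on log2 of the deposited FPKM plus a pseudocount of 1 or 0.1 for genes with FPKM of at least 1, and the estimated correlation without DMSO 11. GC content and length came from the longest transcript per gene in GENCODE release v29, which covered 97.8% of tested genes.

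The fit was tested on simulated counts for 16961 genes with the means and library sizes of this comparison. It recovered 2 of 67 genes changed 1.5-fold, 25 of 67 changed 2-fold and 63 of 66 changed 4-fold, with 6 calls among 16761 unchanged genes. These simulated libraries had no GC trend and no library that stood apart, unlike the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.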

Results

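Gene expression was measured by poly(A) RNA sequencing in SKOV3, an established human ovarian cancer line known for amplified ERBB2. Cells had been kept for 48 h with fenbendazole at 1 µM, a benzimidazole drug against parasitic worms that binds tubulin, or with the solvent DMSO. Each group held 3 libraries, with 13170775 to 22128930 counts per library. The design asks how fenbendazole changes the transcriptome of these cells.

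With fenbendazole, 38 of 40 genes of G2 and mitosis and 33 of 40 DNA replication genes rose. Of 22 repair genes, all of homologous recombination or the Fanconi anemia pathway, 14 rose. Also higher were 7 of 22 genes of cytokines and NF-kB targets and 6 of 13 histone genes, and 4 of 12 ovarian carcinoma markers fell. With an estimated correlation, the list tests gave an adjusted p of 0.0548 for mitosis and 0.0418 for replication, cytokine and histone genes. It was 0.0752 for repair and 0.176 for ovarian genes. Without DMSO 11, a control library that stood apart, it was 0.137 for each of these lists but the ovarian one, at 0.2. Fewer libraries reduce the power of this test, so that loss alone does not show that the changes rest on DMSO 11. AURKA, a mitotic kinase, rose from 21.99 ± 2.20 to 165.6 ± 0.860 CPM (SD, n = 3 each), a 7.52-fold difference. CCNB1, which encodes cyclin B1, rose 5.50-fold, and F3, which encodes tissue factor, rose 4.67-fold from 155.5 ± 23.2 to 725.1 ± 24.9 CPM. CD24, a surface glycoprotein, fell from 751.0 ± 92.2 to 322.1 ± 8.29 CPM. Of 17363 genes tested with edgeR's quasi-likelihood test, 700 passed a Benjamini-Hochberg adjusted p of 0.05, 540 higher and 160 lower with fenbendazole. Upper-quartile scaling gave 455 higher and 231 lower genes, and offsets for GC content and length gave 1979 and 1701. One control library, DMSO 11, stood apart from the other 5. Without it 3946 of 17689 genes passed, among them 538 of the 540 higher and all 160 lower genes. That fit drops the most deviant control, so its p-values, here and below, may understate the spread between controls. The count of genes past the threshold was 278 without DMSO 10 (248 higher and 30 lower). It was 147, 152 and 149 without fenbendazole 7, 8 and 9, each time with 8 lower.

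**Figure D1:**
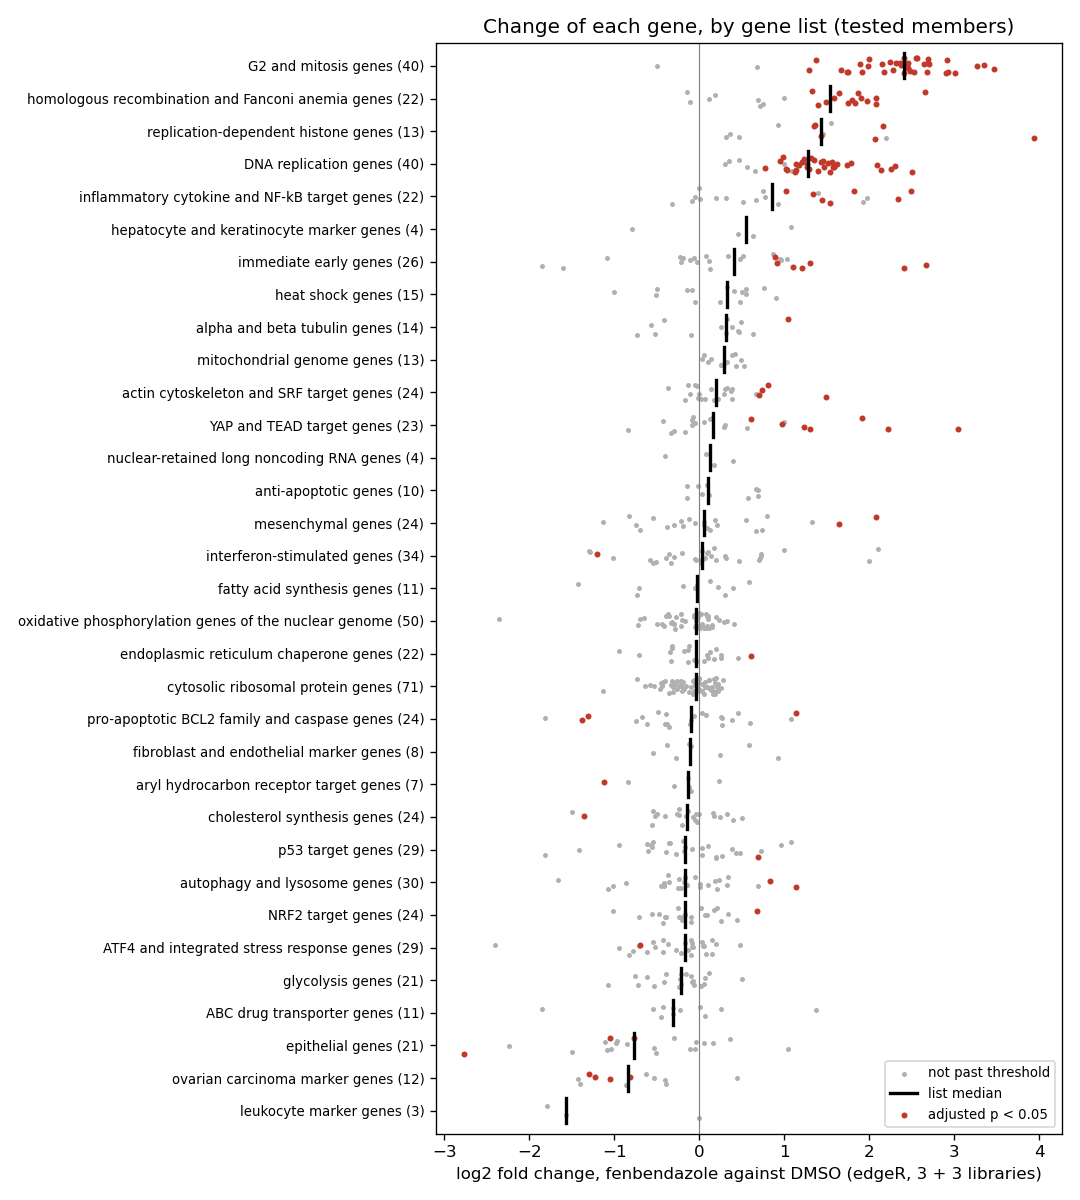
Log2 fold change (fenbendazole against DMSO, x axis) of each tested member of 33 gene lists, with the number of tested members in brackets. Red points passed an adjusted p of 0.05 in edgeR's test, grey points did not, and black bars are list medians, which run from 2.41 for the G2 and mitosis genes to -1.56 for the 3 tested members of the leukocyte list, which did not pass its test and of which HBA1 and HBB are haemoglobin genes.

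The G2 and mitosis genes changed most. Of 40 members 38 rose and 0 fell, with a median log2 fold change of 2.41, and camera gave the list an adjusted p of 3.34e-40 (adjusted p = 0.0548 with an estimated correlation). With an estimated correlation and DMSO 11 left out, the adjusted p of this list was 0.137. Adjusted over the list alone, 39 rose and 1 fell. KIF20A, a kinesin of cytokinesis, had a log2 fold change of 2.90 ± 0.149 (SE), CKS2, a cyclin-dependent kinase subunit, 2.70 ± 0.137, and MKI67, which encodes the proliferation marker Ki-67, 2.48 ± 0.200. Of the 8 largest rises among genes past the threshold with a mean of at least 5 CPM and groups that did not overlap, HMMR (3.47 ± 0.421), DLGAP5 (3.34 ± 0.261), KIF14 (3.27 ± 0.405) and CENPE (3.01 ± 0.440) are members of this list. CEP55 (3.15 ± 0.234), which acts in abscission, the kinase gene PBK (2.98 ± 0.336), SCEL (2.97 ± 0.485), which encodes a protein of the cornified envelope, and ARHGAP11A (2.93 ± 0.238), whose reads may be shared with a near-identical paralog, were the others. Without DMSO 11 each of these 8 rises was smaller. HMMR, DLGAP5, KIF14 and CENPE then rose by 3.09, 3.10, 2.94 and 2.68. CEP55, PBK, SCEL and ARHGAP11A rose by 2.93, 2.67, 2.57 and 2.72, and AURKA, not among the 8, by 2.93. The calls of CENPE and SCEL were lost without DMSO 10 (adjusted p = 0.0674 and 0.087) and without fenbendazole 7 (0.0661 and 0.0929). They were lost too without fenbendazole 9 (0.0711 and 0.0963), and that of SCEL also without fenbendazole 8 (0.076).

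Genes of DNA replication, homologous recombination and the Fanconi anemia pathway rose with them. Of 40 replication genes 33 rose and 0 fell, with a median of 1.28 (camera adjusted p = 8.35e-33, and adjusted p = 0.0418 with an estimated correlation), and 37 rose adjusted over the list alone. TYMS, thymidylate synthase, had a log2 fold change of 2.30 ± 0.178 (SE), RRM2, a subunit of ribonucleotide reductase, 2.14 ± 0.154, and CDC6, which loads the replicative helicase, 1.78 ± 0.140. Of 22 genes of homologous recombination and the Fanconi anemia pathway 14 rose and 0 fell, with a median of 1.54 (camera adjusted p = 3.06e-14, and adjusted p = 0.0752 with an estimated correlation). FANCI, FANCD2 and EXO1 were 3.56, 3.01 and 3.74 times higher, and 18 rose adjusted over the list alone. Of 13 replication-dependent histone genes 6 rose and 0 fell (camera adjusted p = 1.01e-08, and adjusted p = 0.0418 with an estimated correlation), and 8 rose adjusted over the list alone. H2BC5 was at 2.60 ± 0.468 CPM in DMSO and 11.6 ± 0.572 with fenbendazole. Most such transcripts lack a poly(A) tail and their sequences are alike, so these counts are uncertain. With an estimated correlation and DMSO 11 left out, the adjusted p was 0.137 for each of the replication, repair and histone lists. The number of replication genes that rose was 15, 13 and 14 without fenbendazole 7, 8 and 9, of repair genes 6, 7 and 6, and of histone genes 1 each. Without DMSO 10, 22 replication genes and 1 histone gene rose, and without DMSO 12, 1 histone gene rose.

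**Figure D2:**
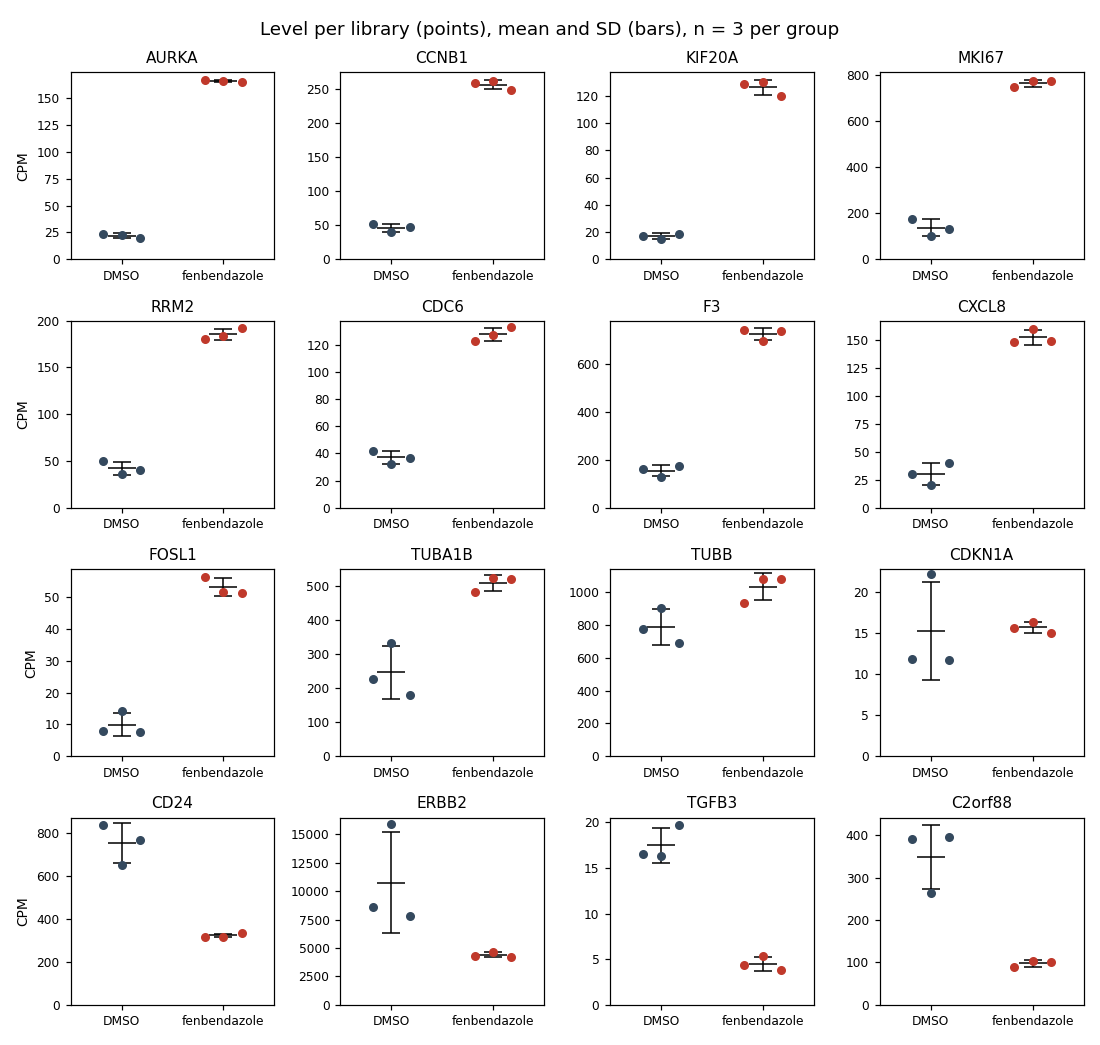
Level of 16 named genes in CPM (y axis from 0) in each library (points) for DMSO and fenbendazole, with the mean and SD of 3 libraries (black bars). AURKA lies at 21.99 CPM in DMSO and 165.6 CPM with fenbendazole, and CDKN1A, at 15.2 and 15.7 CPM, overlaps between the groups.

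Cytokine, immediate early and YAP target genes rose in part. Of 22 genes of inflammatory cytokines and NF-kB targets 7 rose and 0 fell, and 12 rose adjusted over the list alone (camera adjusted p = 1.41e-08, and adjusted p = 0.0418 with an estimated correlation). CXCL8, a neutrophil chemokine, rose from 30.3 ± 10.2 to 152.7 ± 6.78 CPM, and TNFAIP3 and CXCL1 rose 2.53-fold and 2.03-fold. Of 26 immediate early genes 7 rose, led by FOSL1, an AP-1 subunit, at 5.32-fold (list adjusted p = 9.32e-05, and adjusted p = 0.453 with an estimated correlation), and 11 rose adjusted over the list alone. Of 23 YAP and TEAD targets 7 rose, among them F3, CCN1 (2.47-fold) and the receptor kinase gene AXL (2.35-fold), and 8 rose and 1 fell adjusted over the list alone (list adjusted p = 0.00273, and adjusted p = 0.111 with an estimated correlation). Of 24 actin and SRF target genes 4 rose, including TAGLN (2.81-fold) and TPM4 (1.75-fold), and 6 adjusted over the list alone (list adjusted p = 0.00273, and adjusted p = 0.453 with an estimated correlation; 0.0789 without DMSO 12). With an estimated correlation and DMSO 11 left out, the adjusted p was 0.137 for the cytokine and immediate early lists and 0.348 for the YAP target and actin lists. Without DMSO 11 the members that rose numbered 14 cytokine, 16 immediate early, 11 YAP target and 17 actin genes, and 3 YAP targets and 0 of the other lists fell. Without fenbendazole 7, 8 and 9 they numbered 1, 1 and 2 cytokine, 1, 1 and 2 immediate early, 3, 3 and 4 YAP target genes and 0 actin genes each, and without DMSO 10 they numbered 4, 2, 6 and 2. The calls of CXCL1, TAGLN and TPM4 were lost without each of fenbendazole 7 (adjusted p = 0.083, 0.0585 and 0.0748), 8 (0.0774, 0.0626 and 0.0734) and 9 (0.059, 0.07 and 0.07), and that of TNFAIP3 without 7 (0.052) and 8 (0.0506).

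Some markers of ovarian carcinoma and a few epithelial genes fell. Of 12 ovarian carcinoma markers 4 fell and 0 rose, with a median of -0.84 (camera adjusted p = 1.35e-05, and adjusted p = 0.176 with an estimated correlation), and 7 fell adjusted over the list alone. CD24, which has pseudogenes that may share its reads, changed by -1.22 ± 0.130 (SE), ESR1, the estrogen receptor, by -0.82 ± 0.122 and MUC1, a mucin, by -1.05 ± 0.198. ERBB2, which encodes the receptor kinase HER2 (ENSG00000141736, chromosome 17, 39687914 to 39730426, GRCh38), was among the 5 genes of the highest level and changed by -1.29 ± 0.265 (adjusted p = 0.0422). It stood at 10757 ± 4455 CPM in DMSO and 4394 ± 212.3 CPM with fenbendazole, and its change was -0.89 ± 0.0585 without DMSO 11. Its annotated span overlaps PGAP3 and MIEN1, so reads may be shared. Of 21 epithelial genes 3 fell (TJP3, MUC1 and CDH1), and 7 fell and 1 rose adjusted over the list alone. The list's adjusted p was 0.00478 (adjusted p = 0.453 with an estimated correlation) and its median was -0.76. Without DMSO 11 the adjusted p was 0.107 and the median -0.01. The calls of ESR1, MUC1 and ERBB2 were lost without DMSO 10 (adjusted p = 0.0602, 0.0933 and 0.0797) and without fenbendazole 7 (0.111, 0.153 and 0.198), 8 (0.102, 0.146 and 0.168) or 9 (0.102, 0.184 and 0.206), and that of MUC1 with GC offsets, where its change was smaller (-0.50 ± 0.306, adjusted p = 0.305). Without DMSO 11, 8 ovarian markers and 6 epithelial genes fell. Without DMSO 10, 1 of each fell, and without fenbendazole 7, 8 and 9, 1 ovarian marker and 0 epithelial genes fell each time.

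The 8 largest falls were taken among genes past the threshold with a mean of at least 5 CPM and groups that did not overlap. C2orf88 (ENSG00000187699, chromosome 2, 189879609 to 190203484) fell from 349.9 ± 75.3 to 97.8 ± 7.999 CPM, and TGFB3, a growth factor of the TGF-beta family (ENSG00000119699, chromosome 14, 75958097 to 75983011), fell from 17.5 ± 1.92 to 4.49 ± 0.793 CPM. HSD11B2, which inactivates cortisol, changed by -2.56 ± 0.488, the noncoding RNA LINC02593 by -2.46 ± 0.413, LYNX1 by -1.90 ± 0.320, the lipase gene LIPG by -1.89 ± 0.255, the kinesin gene KIF12 by -1.83 ± 0.380 and the receptor gene QRFPR by -1.81 ± 0.297. C2orf88 and TGFB3 passed the threshold without each library in turn. The others did not pass it without fenbendazole 7 (adjusted p from 0.0637 to 0.204), 8 (0.0619 to 0.189) or 9 (0.0618 to 0.201), and HSD11B2, LINC02593, KIF12 and QRFPR also not without DMSO 10 (0.0545 to 0.0789). Without DMSO 11, KIF12 changed by -1.25, HSD11B2 by -1.97, LINC02593 by -1.94, LYNX1 by -1.50, LIPG by -1.81 and QRFPR by -1.65. C2orf88 and TGFB3 changed by -2.001 and -2.005 in that fit.

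Tubulin genes, whose products the drug binds, gave 1 rise and 0 falls among 14 (adjusted p = 0.2). TUBA1B rose from 246.8 ± 77.9 to 507.5 ± 22.9 CPM (adjusted p = 0.0457), a call lost without DMSO 10 (adjusted p = 0.142), without DMSO 12 (0.0716) and without fenbendazole 7, 8 and 9 (0.174, 0.184 and 0.197), and with upper-quartile scaling (0.0501). TUBB had a log2 fold change of 0.39 ± 0.140 (adjusted p = 0.174). Without DMSO 11, 7 tubulin genes rose and 0 fell, and the list's adjusted p was 0.000885 (adjusted p = 0.348 with an estimated correlation). Sequences of tubulin genes are alike, so reads may be shared between them. CYP1A1, a target of the aryl hydrocarbon receptor, had 0, 3 and 2 counts in DMSO and 4, 3 and 7 with fenbendazole. It was removed by the filter on low counts, and its adjusted p was 0.561 in the fit with no filter. CDKN1A, which encodes the cell cycle inhibitor p21, had a log2 fold change of 0.04 ± 0.277 (adjusted p = 0.951), and it was 0.42 (adjusted p = 0.0705) without DMSO 11. Of 29 p53 targets 1 rose, PLK2, a call lost without DMSO 10 (adjusted p = 0.0984) and without fenbendazole 7, 8 and 9 (0.12, 0.142 and 0.153). Without DMSO 11, 6 p53 targets rose and 3 fell.

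Metabolic and stress genes gave few calls with all 6 libraries and more without DMSO 11. Of 21 glycolysis genes, 50 nuclear genes of oxidative phosphorylation and 71 ribosomal protein genes, 0 passed the threshold, and the lists' adjusted p were 0.203, 0.468 and 0.686. Without DMSO 11, 2 glycolysis genes rose and 4 fell, 1 and 3 of oxidative phosphorylation, and 4 and 1 ribosomal protein genes. Over all genes in that fit, 3946 of 17689 passed the threshold, against 700 of 17363 with all libraries. HK2, a hexokinase, had a log2 fold change of -0.06 ± 0.139 and SLC2A1, a glucose transporter, -0.42 ± 0.265, which was -0.03 without DMSO 11. GAPDH was at -0.21 ± 0.167, and at 0.03 with offsets for GC content. ACTB was at 0.22 ± 0.274, and at 0.65 (adjusted p = 4.95e-06) without DMSO 11. The 13 genes of the mitochondrial genome had a median of 0.29 and 0 members past the threshold (list adjusted p = 0.00872, and adjusted p = 0.607 with an estimated correlation), and mitochondrial genes took 3.17% of counts in DMSO 11 and 3.79% to 4.19% in the other 5 libraries. The adjusted p of the ATF4 and heat shock lists was 0.0601 each, with 1 of 29 members (DDIT3) lower and 0 of 15 past the threshold. The call of DDIT3 was lost without DMSO 10 (adjusted p = 0.106), without DMSO 12 (0.0874) and without fenbendazole 7, 8 and 9 (0.203, 0.156 and 0.228). Without DMSO 11, 1 ATF4 target rose and 8 fell (list adjusted p = 0.152), 8 heat shock genes rose and 0 fell (0.0224, and adjusted p = 0.541 with an estimated correlation), and 5 mitochondrial genes rose and 0 fell (0.0251, and adjusted p = 0.761 with an estimated correlation). Of the 33 lists, 11 passed camera's test and 3 of these held with an estimated correlation: DNA replication, histone and cytokine genes. Without DMSO 11, 0 of the 11 held with an estimated correlation, with adjusted p from 0.137 to 0.761. That fit held fewer libraries, which reduces the power of this test, so it does not show that the lists were unchanged. Of 64 named genes past the threshold, 27 passed it without each library in turn, among them AURKA, CCNB1, MKI67, F3, CXCL8, CD24 and C2orf88.

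**Figure D3:**
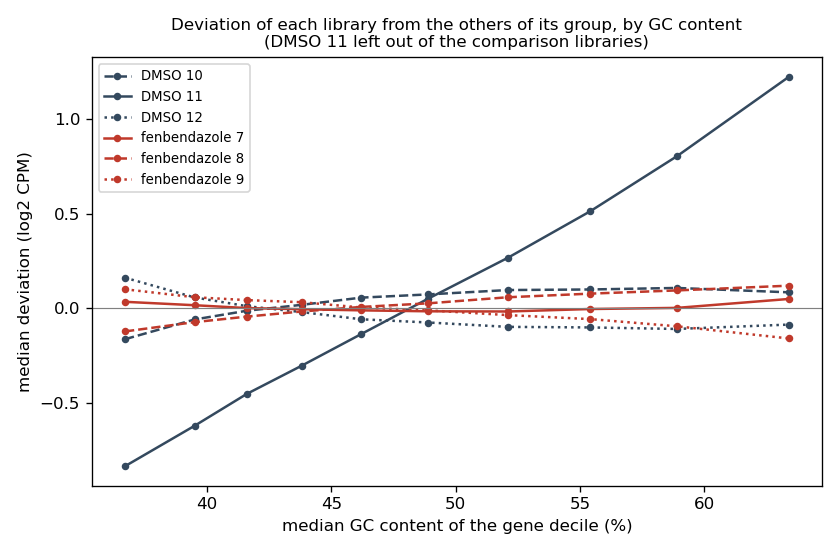
Median deviation (log2 CPM, y axis) of each library from the other libraries of its group, DMSO 11 left out of the comparison libraries, in 10 groups of genes by GC content (x axis, percent). DMSO 11 runs from -0.83 at 36.7% GC to 1.22 at 63.4% GC.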

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

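The GC and length offsets, quality weights, FPKM fits and the estimated correlation without DMSO 11 were chosen after seeing the data. No paired analysis was possible because the groups share no replicate numbers. No call of a list or named gene turned direction, and 0 genes were called in opposite directions in any fit. Against 700 genes (540 higher, 160 lower), DESeq2 gave 1963 (1155 and 808), GC and length offsets 3680 (1979 and 1701), quality weights 4587 (2434 and 2153; weight of DMSO 11 0.074), an adjusted p of 0.01 gave 210 (193 and 17), the test against a 1.5-fold change 214 (200 and 14), and a fold of at least 2 left 85 lower. Leaving out 1 library gave 147 to 3946 genes, 139 to 2313 higher and 8 to 1633 lower. Fewer libraries reduce power, and the rise without DMSO 11 goes with its large spread. The p-values without DMSO 11 may therefore understate the spread between controls. Other scalings and filters, voom and FPKM gave 647 to 858. With an estimated correlation the adjusted p was 0.0548 for mitosis, 0.0752 for repair, 0.453 for immediate early, actin and epithelial, 0.111 for YAP target, 0.176 for ovarian marker and 0.607 for mitochondrial genes; without DMSO 11 it was 0.137 for mitosis, replication, repair, cytokine, immediate early and histone, 0.348 for YAP and actin, 0.2 for ovarian, 0.758 for epithelial and 0.761 for mitochondrial genes. Fry called anti-apoptotic (0.00105), aryl hydrocarbon receptor (0.0152), heat shock (0.0228) and ABC transporter genes (0.0479) but not immediate early (0.0551), actin (0.0858), epithelial (0.101) or mitochondrial genes (0.125); it does not compare a list with other genes. The ATF4 list passed with upper-quartile scaling (0.0347), no filter (0.0181) and FPKM (0.017 and 0.0231). The heat shock list passed with no filter (0.0441), GC offsets (0.0275) and FPKM (0.044), and the tubulin list with GC offsets (0.00355). With all libraries and an estimated correlation, the adjusted p of the ATF4, heat shock and tubulin lists was 0.653, 0.453 and 0.857. Without 1 library the adjusted p ran from 0.000885 to 0.824 for tubulin, 0.03 to 0.162 for ATF4, 0.0224 to 0.22 for heat shock, 9.03e-08 to 0.0789 for actin, 0.00271 to 0.107 for epithelial, 0.0433 to 0.868 for glycolysis and 0.021 to 0.628 for the leukocyte list. Of 64 named calls, 28 were lost without DMSO 10, 11 without DMSO 12, 36 without each treated library, 5 with upper-quartile scaling, 2 with GC offsets and 0 without DMSO 11 or with DESeq2, and 12 of 63 with FPKM. Otherwise the cause was not tested. In simulation edgeR recovered 37.3% and DESeq2 67.2% of 2-fold changes, with 6 and 58 false calls among 16761 unchanged genes. True calls at 1.5-fold, 2-fold and 4-fold numbered 2, 25 and 63 for edgeR and 9, 45 and 66 for DESeq2. A larger share of the simulated calls was thus false with DESeq2. The simulated libraries held no GC trend and none that stood apart, so these figures may not carry over to the data.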

Other observations

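The tests of mitotic arrest, of tubulin RNA and of the ERBB2 region, and the second GC test of DMSO 11, were chosen after the results they concern had been seen, as were the GC offsets.

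Several gene groups gave results not described so far. Of 24 NRF2 targets TXNRD1 rose (list adjusted p = 0.571), and of 22 chaperones of the endoplasmic reticulum DNAJB11 rose (0.842). Of 24 pro-apoptotic genes CYCS rose and CASP10 and BMF fell (0.867), while 0 of 10 anti-apoptotic genes passed the threshold (0.133). TNC, from the list of 24 mesenchymal genes, rose 4.24-fold (0.253), and of 30 autophagy and lysosome genes ATG12 and GLA rose (0.571). IFI35 fell among 34 interferon-stimulated genes (0.823), TM7SF2 among 24 cholesterol synthesis genes (0.468) and LRAT among 7 aryl hydrocarbon receptor targets (0.236). Of 11 fatty acid synthesis genes (0.904), 11 ABC transporters (0.203), 4 nuclear noncoding RNAs (0.904), 3 members of the leukocyte list, CD68 and the haemoglobin genes HBA1 and HBB (0.148), 8 fibroblast and endothelial markers (0.571) and 4 hepatocyte and keratinocyte markers (0.148), 0 passed the threshold in edgeR's test. Without DMSO 11, 3946 of all 17689 tested genes passed the threshold. In that fit the genes that rose and fell numbered 4 and 5 for NRF2, 3 and 4 for chaperones and 5 and 3 for pro-apoptotic genes. They numbered 4 and 0 for anti-apoptotic, 9 and 2 for mesenchymal and 6 and 7 for autophagy and lysosome genes. For interferon-stimulated, cholesterol and aryl hydrocarbon receptor genes they numbered 4 and 7, 3 and 4, and 1 and 3. They numbered 4 and 3 for fatty acid synthesis (12 tested), 1 and 3 for ABC transporters, 0 and 1 for the leukocyte list, 3 and 0 for hepatocyte and keratinocyte markers, and 0 for the noncoding RNAs and the fibroblast and endothelial markers (7 tested). Camera's direction was up and the median below 0 for the p53 targets (-0.17), the chaperones (-0.04), fatty acid synthesis (-0.02) and fibroblast and endothelial markers (-0.11, with a mean of 0.045). Of the 2 metallothionein genes tested, MT2A rose 2.38-fold. The genes named in this paragraph as risen or fallen lost their call without each of fenbendazole 7, 8 and 9, with adjusted p from 0.0593 to 0.236, except MT2A, which kept it without 7 (0.0476). Without DMSO 10 they lost it too (0.052 to 0.132), except TNC (0.0163), and without DMSO 12 TXNRD1, DNAJB11, BMF, GLA, TM7SF2 and LRAT lost it (0.0562 to 0.0897). With upper-quartile scaling TXNRD1, DNAJB11, GLA and CYCS lost it (0.0555, 0.0705, 0.0534 and 0.0596). With GC offsets the log2 fold change of DNAJB11 went from 0.613 ± 0.127 (SE) to 0.265 ± 0.146, and its call ended with the smaller change (adjusted p = 0.244).

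The direction of the mitosis genes, higher with a drug that binds tubulin, rests on the labels: a reversal of all 6 would turn this and every other printed direction, and no value in the tables decides on it. A GC and length bias of DMSO 11 and the scaling between libraries do not account for it, since the list median stayed at 2.274 or more without DMSO 11 and with GC offsets, and at 2.332 or more over the other scalings. If cells were only held in mitosis, the replication genes were expected at or below 0. Their median was 1.322 without DMSO 11. That expectation assumes that mitotic cells hold no more replication RNA than other cells, which was not measured, so this explanation stays open. A larger share of DMSO cells out of the cycle, for example from crowding at 48 h, may contribute, and cell density is not given in the labels. Without DMSO 11, 15 quiescence genes had a median of -0.229, which lies between both bounds set beforehand. Camera gave this list p = 0.000421, and p = 0.0328 with an estimated correlation. These p-values are not adjusted, so they cannot be set beside the adjusted p of the other lists. Of the 15 genes, 5 fell and 0 rose past the threshold in that fit. With all libraries 0 fell and 0 rose. Of the 10 splits of the 6 libraries 1, the real one, gave as many as 700 genes and the highest other gave 0, and 10 splits are too few for a share under 0.05.

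DMSO 11 deviated from the other DMSO libraries along GC content, which explained 69% of the variance of its deviation between genes. The test as first set also required its slope to exceed 3 times that of each other library, and this was not met (0.75 against -0.44 for DMSO 12, log2 per 10% GC), because DMSO 10 and 12 were each compared with a mean that held DMSO 11; that test therefore left GC bias undecided. With DMSO 11 left out of those means, a comparison chosen after this outcome, its slope was 8.12 times the next largest, consistent with a GC bias of that library. A treated library under a DMSO label is argued against by its mitosis genes, which lay 2.604 (log2) below the lowest treated library. Where this deviation arose, in the cells, the preparation or the sequencing, was not tested and stays open.

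Drugs that depolymerise microtubules are known to lower tubulin RNA through free tubulin. The hypothesis that this was visible at 48 h as a net fall is argued against by the tubulin median of 0.712 without DMSO 11, with 7 of 14 genes higher and 0 lower. The median was 0.32 with all libraries (1 higher, 0 lower), 0.199 without DMSO 10 and 0.058 without DMSO 12 (0 past the threshold in both). A fall masked by tubulin genes that follow the cell cycle stays open.

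ERBB2 and some close neighbours were lower. Without DMSO 11, PPP1R1B and GRB7 changed by -0.91 and -0.93. MIEN1, whose annotated span overlaps that of ERBB2, changed by -0.93, and reads may be shared. STARD3, which lies between PPP1R1B and ERBB2, changed by -0.24 ± 0.0694 (SE). PGAP3, which follows STARD3 and overlaps the annotated span of ERBB2, changed by -0.35 ± 0.0975, and reads may be shared. These genes were named after their values were seen. A lower copy number of the whole segment within 250 kb was tested on 12 genes, of which 8 passed the threshold as lower and 0 as higher, with a median of -0.374, and 2 lay above 0, MED1 (0.06 ± 0.0585, SE) and ORMDL3 (0.15 ± 0.0933), each within 2 SE of 0, so that count alone is weak. In a further test, MED1, CDK12 and ORMDL3 lay above ERBB2 by at least 0.869, more than 0.3 plus 2 SE, which argues against a change shared by the whole segment. Without DMSO 11, STARD3 and PGAP3 lay above ERBB2 by at least 0.542, again more than 0.3 plus 2 SE. In that fit this argues against a change shared from PPP1R1B to GRB7. Both tests of differences combined the SE of each gene as if they were independent, though the genes were measured in the same libraries. With all libraries STARD3, PGAP3 and ERBB2 changed by -0.566 ± 0.227, -0.817 ± 0.306 and -1.292 ± 0.265 (SE). The differences between them were not tested with all libraries. A change limited to part of the segment, such as ERBB2 to IKZF3 (-0.895 ± 0.302, beyond GRB7), or regulation shared by these genes, stays open.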
